A study of Homo sapiens with 8 samples.

How the data were processed

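Gene expression was measured in BE(2)-C cells, a human neuroblastoma line with MYCN amplification, on 8 Affymetrix Human Gene 1.0 ST arrays. The cells received vehicle, JQ1, nanaomycin or both drugs for 6 hours, with 2 arrays in each of the 4 groups. JQ1 blocks the bromodomains of the BET family of chromatin readers, and nanaomycins are quinone antibiotics, of which nanaomycin A is known as an inhibitor of the DNA methyltransferase DNMT3B. Total RNA was isolated with a column kit and turned into biotin-labelled cRNA, per the labels' protocols.

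The deposited values are 1 number per probe set and array, and their range, from 2.59 to 14.5, fits a log2 signal, so they were used as deposited. The submitters' processing notes name MAS5. How that method was applied to this array type, how the values were put on the log2 scale and how arrays were scaled to each other are not given in the sources used here. No value below a detection limit was removed and no further scaling was applied.

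Of the 32321 probe sets, 19158 carry 1 gene symbol, 1388 carry several and 11775 carry none. The symbols of 19128 of the 1-symbol probe sets matched the RefSeq gene table by Entrez ID, 30 did not match, and 0 symbols had to be updated. A gene was represented by its probe set with the highest mean over all 8 arrays, and probe sets whose mean lay in the upper 50% of the table, above 7.11, were tested. This left 11354 genes, of which 347 have more than 1 probe set above that limit. Probe sets with several symbols were not tested. MYC, with a mean of 6.77, lies below the limit and was not tested. Affymetrix control probe sets for the 3' and 5' ends of transcripts, planned as a sign of RNA quality, were not used here.

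Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the mean) in 1 linear model with a coefficient for each of the 4 groups, which leaves 4 residual degrees of freedom. The 6 comparisons were each drug against vehicle, the combination against vehicle and against each drug alone, and the interaction, which is the combination minus nanaomycin less the JQ1 minus vehicle difference. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors are limma's standard errors of a log2 fold change, or the SD of the 2 arrays of a group.

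Gene lists were tested with limma's camera at its preset correlation between genes of 0.01, with adjustment over the lists of a comparison. The 30 lists hold 582 memberships, and 24 lists had at least 5 measured members. Members were counted as higher or lower over all genes, and again with p-values adjusted over the list alone. For a list called in a comparison of 2 groups, a second count that is not given equals the first. Camera with a correlation estimated from the residuals and the fry test were run beside it. With 4 residual degrees of freedom that estimate is imprecise, and every list called with the preset correlation lost its call with the estimated one.

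The comparisons, the tests, the filter, the lists and the rule for named genes were chosen before the data were examined. The rule takes, in each comparison, the 8 largest rises and the 8 largest falls among genes with an adjusted p below 0.05 whose 2 arrays of a group both lie beyond both arrays of the other. It adds up to 3 members of each list with the largest change, and always names a fixed set of genes, of which 1 is not reported here (the others are HEXIM1, MYCN, MYC, HMOX1, NQO1, TXNRD1, SRXN1, GCLM, CAT, NFE2L2, BRD3, BRD2, DNMT3B, CDKN1A and BCL2). For the interaction it takes the 5 largest terms each way, or the 5 smallest p-values where fewer than 5 genes pass. Genes outside this rule are said to be chosen after their values were seen.

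The deposited values carry a mark of an adjustment by replicate number. In each probe set, the mean over the 4 arrays numbered 1 nearly equals the mean over the 4 arrays numbered 2: the SD of their difference over probe sets was 0.00761, against 0.0795 if the replicate differences of the groups were independent, and 97.7% of probe sets differed by less than 0.02. When the numbers were swapped in 1 to 3 groups the median SD was 0.0811, and the lowest 0.0753. No source used here names such a step, so it is a measured property of the values. It forces the replicate differences of the 4 groups to sum to about 0, so their correlations between groups (mean -0.330, where a zero sum forces -0.333) cannot show whether equal numbers share a culture or a day. It also makes the spread within groups smaller than it would have been. The fit without a replicate block had been chosen before the data were examined and was kept, and the counts of a fit with the replicate block (3 residual degrees of freedom) stand beside counts of at least 3 genes that it moves by more than 1.5 times.

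The scripts were tested on simulated data: 20 simulations of JQ1 versus vehicle with 11354 genes and 200 changed genes. The means of the replicate numbers were removed from the simulated values described next. In the simulated nanaomycin versus vehicle comparison, where no gene was changed, 9.19% of genes had p below 0.05 without the block and 4.92% with it. For JQ1 versus vehicle the share of false calls at the 0.05 threshold was 8.50% without the block and 7.42% with it. Changes of 0.25, 0.5 and 1 were found in 43.3%, 96.7% and 100% of genes without the block and in 40.7%, 98.4% and 100% with it, and 0 calls had the wrong sign. A simulated list of 20 genes raised by 0.2 had p = 9.24e-32 in camera with the preset correlation and p = 0.00134 with an estimated one, and an unchanged list had p = 0.298 and p = 0.444. The simulated genes were drawn independently of each other, so these lists cannot show whether the preset correlation suits the arrays. On the arrays the estimated correlations of the tested lists ran from -0.0537 (metallothioneins) to 0.510 (heat shock).

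The labels do not say that the 2 replicates of a group are separate cultures, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of every value. Alternatives were the replicate block, quantile normalization, arrays centred on their median, 16 or 64 added to the linear value, no filter on mean level or the upper 30%, the mean of a gene's probe sets, eBayes without the trend or with robust estimation, a fit to only the 2 groups compared, and each of the 8 arrays left out in turn. The tested lists were also run under these alternatives, except both eBayes settings and the fit to only the 2 groups (and the metallothionein and NF-kB target lists with the upper 30%, which leaves them under 5 members), an addition made after the data were examined. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.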

Results

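The data are 8 expression profiles of BE(2)-C cells, 2 for each of vehicle, 500 nM JQ1, 125 nM nanaomycin and both drugs, taken 6 hours after treatment. The array medians lay between 7.07 and 7.15 on the log2 scale. The correlation between the 2 arrays of a group was 0.998 in every group, and the lowest between any 2 arrays was 0.990. The first principal component held 73.3% of the variance and set the 4 arrays with JQ1, at 13.9 to 18.1, apart from the 4 without it, at -17.9 to -14.1. The second component held 15.7%. Each gene named among the largest changes had both arrays of a group beyond both arrays of the other. Values are log2 means with the SD of 2 arrays, or log2 fold changes with their standard errors and limma's adjusted p-values.

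The comparison of JQ1 with vehicle asks what BET inhibition changes in MYCN-amplified cells within 6 hours. HEXIM1, which holds the elongation kinase P-TEFb in an inactive complex and is a known marker of BET inhibition, rose 2.94-fold, from 9.35 ± 0.05 to 10.91 ± 0.05 (SD, n = 2; adjusted p = 2.71e-06). TUFT1 (1.56 ± 0.07), the adaptor gene PAG1 (1.52 ± 0.06), the ephrin ligand gene EFNB2 (2.83-fold, SE 0.14 on the log2 scale) and the elongation factor gene ELL2 (1.43 ± 0.14) were among the other largest rises. DKK1, a secreted inhibitor of Wnt signalling, fell 4.67-fold, from 10.98 ± 0.33 to 8.76 ± 0.28 (adjusted p = 3.61e-05). SLC7A11, the cystine transporter subunit, fell by 2.15 ± 0.32 (SE). PALMD fell by 1.99 ± 0.10, ICAM2 by 1.78 ± 0.07, TNS3 by 1.75 ± 0.06 and the growth factor gene HGF by 1.73 ± 0.11. MYCN itself stood at 13.65 with vehicle and 13.60 with JQ1, a log2 change of -0.05 ± 0.02 that did not pass (adjusted p = 0.0817). Its signal lay near the highest value of any array, 14.5. Whether such bright signals understate changes, here and in the comparisons below, was not tested.

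Among the target family of JQ1, BRD2 rose by 0.57 ± 0.04 (adjusted p = 1.69e-05). For BRD3 the change was 0.18 ± 0.05 (adjusted p = 0.0238), and its call was lost without the first vehicle array (0.0924), the second vehicle array (0.0543), the first JQ1 array (0.0577) or the second (0.113), with the replicate block (0.0527) and under quantile normalization (0.0587). Of 13 measured members of the BET and P-TEFb list 9 rose, and HEXIM2 fell by 0.59 ± 0.08 (9 and 1 also when adjusted over the list alone; median 0.32). The camera test gave an adjusted p of 0.00167, and adjusted p = 0.377 with an estimated correlation. All 13 measured polyadenylated histone genes, which can give polyadenylated transcripts outside S phase, rose, as they did when adjusted over the list alone (median 0.48, camera adjusted p = 1.75e-07, adjusted p = 0.377 with an estimated correlation). H2BC21 rose by 1.48 ± 0.10, H2BC12 by 1.24 ± 0.08 and H4C8 by 1.11 ± 0.11.

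Of the 24 measured adrenergic neuroblastoma regulators, the transcription factors of the noradrenergic cell state, 14 fell and 3 rose over all genes, and 15 fell and 3 rose adjusted over the list alone (median -0.26). The camera adjusted p was 0.00298, and adjusted p = 0.735 with an estimated correlation. LMO3 fell by 1.51 ± 0.14, LMO1, a transcriptional cofactor linked to neuroblastoma risk, by 1.01 ± 0.07 and TFAP2B by 1.00 ± 0.12. In the G1/S list 10 of 20 genes fell and 2 rose, also adjusted over the list alone (median -0.15, camera adjusted p = 0.0165, adjusted p = 0.735 with an estimated correlation). E2F2 fell by 0.79 ± 0.06, the cyclin gene CCND1 by 0.54 ± 0.04 and the replication helicase gene MCM5 by 0.46 ± 0.04. In the ER chaperone list 10 of 15 genes rose and 1 fell, also adjusted over the list alone (median 0.19, camera adjusted p = 0.0165, adjusted p = 0.735 with an estimated correlation). DNAJC3 rose by 0.67 ± 0.13 and HSPA5 by 0.41 ± 0.04.

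In the immediate early list, genes that respond first to growth signals, 8 of 15 rose and 2 fell, also adjusted over the list alone (median 0.36). Its camera adjusted p was 0.0242, 0.0520 without the first JQ1 array, and adjusted p = 0.735 with an estimated correlation. EGR1 rose by 1.20 ± 0.07 and FOS by 0.81 ± 0.09, while NR4A3 fell by 0.92 ± 0.10. BCL2, which blocks apoptosis, fell by 0.68 ± 0.07 and BCL2L1 by 0.62 ± 0.06, and DNMT3B rose by 0.56 ± 0.07. NQO1, a quinone reductase, fell by 0.23 ± 0.04 (adjusted p = 0.00123) and TXNRD1, thioredoxin reductase, rose by 0.14 ± 0.03 (adjusted p = 0.00535). HMOX1, heme oxygenase, changed by -0.76 ± 0.26 (adjusted p = 0.0342), a call lost without the first vehicle array (0.134) or the second JQ1 array (0.159) and with eBayes without the trend (0.0510) or with robust estimation (0.0613). GCLM, SRXN1, NFE2L2, CDKN1A and CAT did not pass.

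The remaining lists were not called by camera with JQ1. The ribosome biogenesis list, a class of MYC targets, had 5 of 27 genes higher and 7 lower, also adjusted over the list alone (median -0.04, adjusted p = 0.727), with MRTO4 lower by 0.35 ± 0.05 and UTP20 by 0.27 ± 0.04; the fry test gave an adjusted p of 0.0434. The MYC target enzymes list had 3 of 17 higher and 3 lower (adjusted p = 0.877), with CAD lower by 0.34 ± 0.06 and GART by 0.27 ± 0.05, and its median, 0.0127, and mean, -0.00903, differ in sign. The NRF2 target list, genes of the defence against electrophiles, had 6 of 27 higher and 7 lower (adjusted p = 0.605), and its median, 0.08, and mean, -0.04, differ in sign. The p53 target list had 10 of 19 higher and 6 lower (adjusted p = 0.468), with TP53INP1 higher by 0.94 ± 0.14 and TNFRSF10B lower by 0.66 ± 0.06. Among the sympathoadrenal markers (7 of 20 higher, 8 lower, adjusted p = 0.531) the neuronal RNA-binding protein gene ELAVL4 fell by 1.06 ± 0.06 and NEFM rose by 0.60 ± 0.08. Among the mesenchymal neuroblastoma regulators (1 of 17 higher, 4 lower, adjusted p = 0.531) CD44 fell by 1.10 ± 0.08. The G2/M list had 7 of 19 lower and 1 higher (adjusted p = 0.249), with AURKA lower by 0.56 ± 0.06. The BCL2 family list had 7 of 13 lower and 3 higher (adjusted p = 0.444), with PMAIP1 higher by 0.63 ± 0.08.

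Of the stress lists, the integrated stress response had 4 of 20 higher and 1 lower with JQ1 (adjusted p = 0.531), heat shock 1 of 15 higher and 4 lower (0.531), hypoxia and glycolysis 8 of 18 higher and 2 lower (0.468), autophagy and lysosome 6 of 16 higher and 4 lower (0.531), and the proteasome 1 of 28 higher and 7 lower (0.468). KDM3A rose by 0.79 ± 0.08 and the lysosomal sialidase gene NEU1 by 0.68 ± 0.05. Cholesterol synthesis had 5 of 15 higher and 5 lower (0.934), DNA methylation machinery 3 of 12 higher and 3 lower (0.990), metallothioneins 2 of 7 higher and 3 lower (0.696), NF-kB targets 1 of 7 higher and 3 lower (0.468) and reference genes 3 of 10 higher and 0 lower (0.341). For the DNA methylation machinery the median, -0.0174, lies below 0 while the test points up. Lists with fewer than 5 measured members were not tested as lists. With JQ1 these had 0 of 4 methylation-silenced germline genes higher and 1 lower, 1 of 4 interferon response genes higher and 1 lower, 0 of 2 Schwann and glial markers higher and 1 lower, 1 of 2 leukocyte markers higher and 0 lower, 1 of 4 fibroblast markers higher and 1 lower, and 1 of 2 epithelial markers higher and 1 lower. PDGFRB fell by 0.91 ± 0.08 and the glial gene GPM6B by 0.61 ± 0.05.

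Over all genes, 2798 rose and 2732 fell with JQ1, 5530 of 11354. At least 1.5-fold rises numbered 310 and falls 364, and 39 rises and 62 falls reached 2-fold, with a median absolute change of 0.30 among changed genes.

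**Figure D1:**
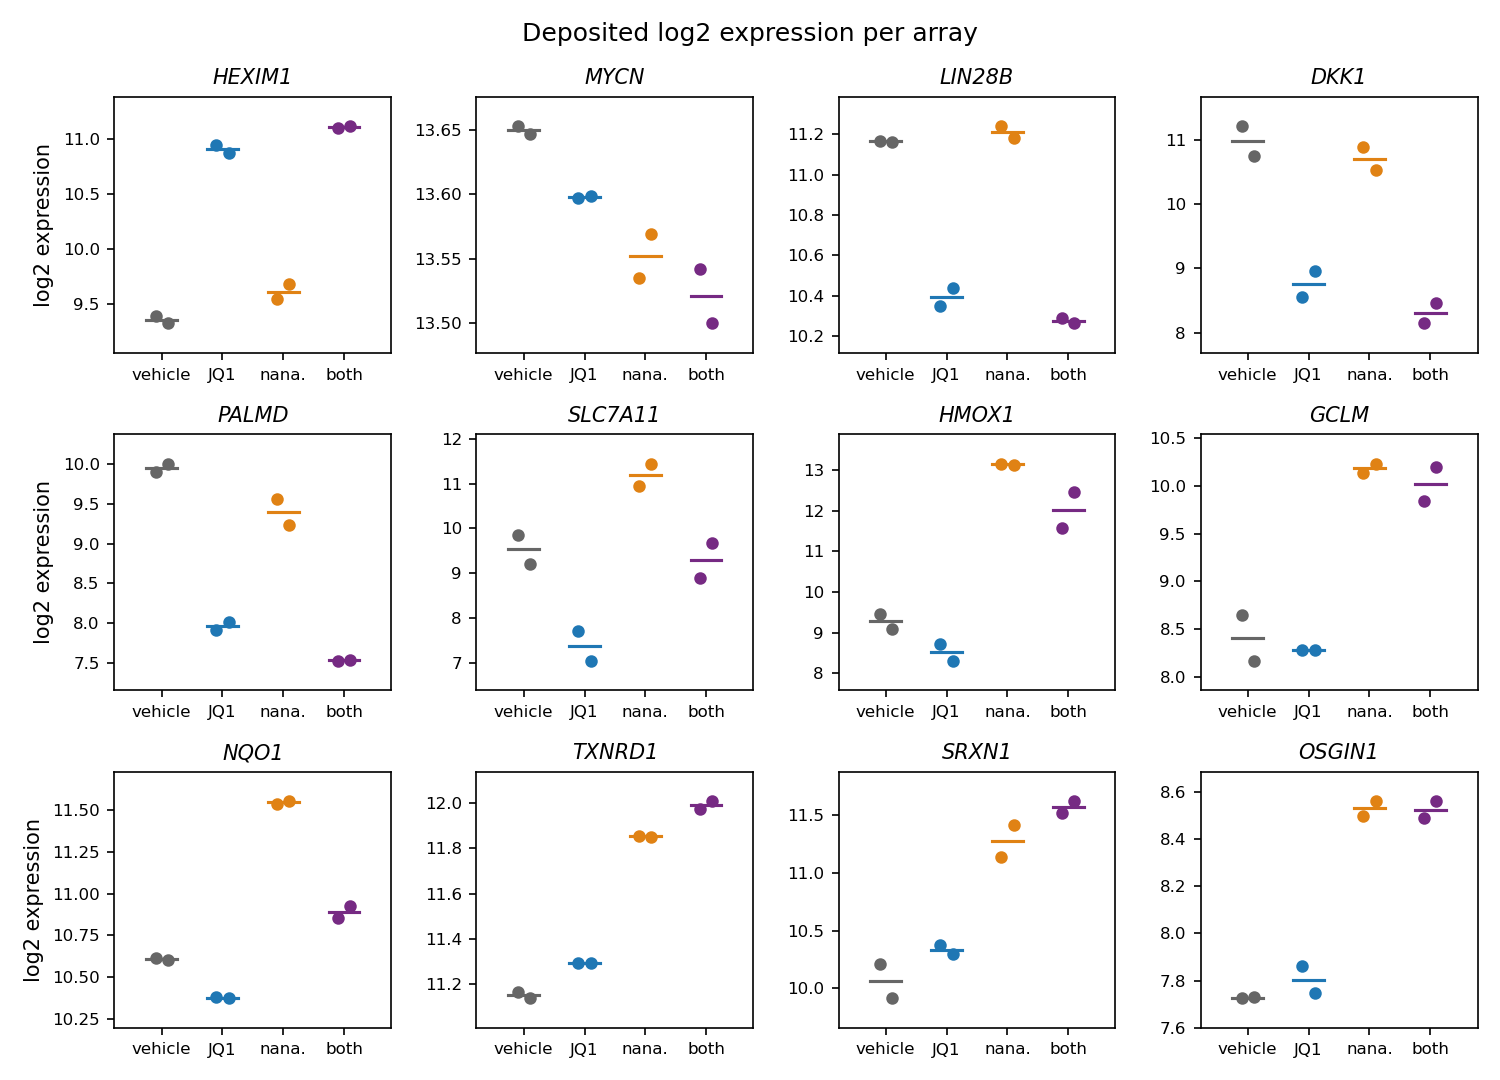
Expression of 12 named genes (log2 signal, y axis, each panel with its own scale) with vehicle, JQ1, nanaomycin and both drugs (x axis); points are the 2 arrays of a group and the line is their mean. HEXIM1 is higher in the 4 arrays with JQ1, and HMOX1, GCLM, TXNRD1 and SRXN1 are higher in the 4 with nanaomycin.

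Nanaomycin against vehicle shows what this quinone changes alone. HMOX1, which degrades heme and is a classic NRF2 target, rose 14.6-fold, from 9.28 ± 0.26 to 13.15 ± 0.02 (SD, n = 2; adjusted p = 0.000324). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 3.44-fold (1.78 ± 0.15, adjusted p = 0.00144) and SRXN1, sulfiredoxin, by 1.22 ± 0.11 (adjusted p = 0.00179). NQO1 rose by 0.94 ± 0.04 (adjusted p = 2.27e-05), TXNRD1 by 0.70 ± 0.03 (adjusted p = 2.32e-05) and the aldo-keto reductase gene AKR1C2 by 1.16 ± 0.07 (adjusted p = 0.000324). The chaperone gene DNAJB4 rose by 1.20 ± 0.12 and PFKFB3, which drives glycolysis, by 1.17 ± 0.12.

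Of 27 measured NRF2 targets 17 rose and 0 fell over all genes, and 20 rose adjusted over the list alone (median 0.30, camera adjusted p = 1.59e-14, adjusted p = 0.232 with an estimated correlation). In the integrated stress response list 10 of 20 rose over all genes and 19 adjusted over the list alone (median 0.40, camera adjusted p = 2.15e-10, adjusted p = 0.232 with an estimated correlation). PPP1R15A, which restores translation after stress, rose by 0.91 ± 0.12 (adjusted p 0.0593 without the second vehicle array). The ER chaperone list had 9 of 15 higher, 12 adjusted over the list alone (median 0.24, camera adjusted p = 5.68e-10, adjusted p = 0.232 with an estimated correlation), with HERPUD1 higher by 0.43 ± 0.04. The proteasome list had 17 of 28 higher, 20 adjusted over the list alone (median 0.13, camera adjusted p = 4.55e-11, adjusted p = 0.232 with an estimated correlation). PSMC6 rose by 0.40 ± 0.05 (adjusted p 0.0593 without the second vehicle array), and with the replicate block 9 proteasome genes passed. The heat shock list had 6 of 15 higher, 12 adjusted over the list alone (median 0.19, camera adjusted p = 8.48e-07, adjusted p = 0.326 with an estimated correlation). The co-chaperone gene BAG3 rose by 0.97 ± 0.14 (adjusted p 0.0543 without the second vehicle array), and 3 heat shock genes passed with the replicate block.

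Immediate early genes rose in 6 of 15 cases, 9 adjusted over the list alone (median 0.21, camera adjusted p = 2.68e-05, adjusted p = 0.270 with an estimated correlation), with JUN higher by 0.67 ± 0.08 and EGR1 by 0.64 ± 0.07. In the hypoxia and glycolysis list 5 of 18 rose, 7 adjusted over the list alone (median 0.09, camera adjusted p = 0.000729, adjusted p = 0.232 with an estimated correlation), and 3 passed with the replicate block. In the autophagy and lysosome list 6 of 16 rose over all genes (median 0.12, camera adjusted p = 0.00370, adjusted p = 0.306 with an estimated correlation), 8 rose and 1 fell adjusted over the list alone, and 3 rose with the replicate block. The lysosomal galactosidase gene GLA was higher by 0.59 ± 0.07. In the cholesterol synthesis list 4 of 15 rose, 8 adjusted over the list alone and 2 with the replicate block (median 0.10). Its camera adjusted p was 0.00697, 0.0520 without the first vehicle array, and adjusted p = 0.232 with an estimated correlation.

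The adrenergic regulators had 8 of 24 lower and 2 higher, 12 and 2 adjusted over the list alone, and 5 lower with the replicate block (median -0.11, camera adjusted p = 6.84e-05, adjusted p = 0.418 with an estimated correlation). LMO3 was lower by 0.75 ± 0.14 (adjusted p = 0.0249), a call lost without the second vehicle array (0.138) or the second nanaomycin array (0.105). The list's median was -0.171 without the first nanaomycin array and -0.0709 without the second. The G2/M list had 0 of 19 genes passing in either direction, also adjusted over the list alone (median -0.05). Its camera adjusted p was 0.00588, 0.182 without the second nanaomycin array (median -0.0261; -0.0895 without the first), and adjusted p = 0.537 with an estimated correlation. Small nucleolar RNA genes, which guide the modification of ribosomal RNA, made up several of the largest falls: SNORA23 fell by 1.22 ± 0.14 (adjusted p = 0.00604) and SNORA3A by 1.05 ± 0.17 (adjusted p = 0.0152, 0.0873 without the second vehicle array).

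DNMT3B, the known target of nanaomycin A, stood at -0.15 ± 0.07 at the RNA level and did not pass (adjusted p = 0.195), and 0 of 12 genes of the DNA methylation machinery list passed in either direction (median -0.09, adjusted p = 0.152, and 0.0478 without the first nanaomycin array). Only 4 of 23 methylation-silenced germline genes were measured, and 0 of these passed. The filter on mean level leaves out genes with low signal, so this count cannot show whether silenced genes rose. MYCN stood at -0.10 ± 0.02 (adjusted p = 0.0363) and HEXIM1 at 0.26 ± 0.06 (0.0322). With the replicate block their adjusted p-values were 0.0842 and 0.0586, and in a fit to only the 2 groups 0.0581 and 0.0557. The MYCN call was lost with no filter (0.0613) and with eBayes without the trend (0.173), and the HEXIM1 call with arrays centred on their median (0.0515). The MYCN call was also lost without the first (0.0773) or second (0.175) vehicle array, the first (0.0538) or second (0.0536) JQ1 array, or the first (0.111) or second (0.0934) nanaomycin array, and the HEXIM1 call without the second vehicle (0.193) or second nanaomycin array (0.165).

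For SLC7A11 the change was 1.66 ± 0.32 (0.0243, but 0.130 without the second vehicle array and 0.0982 without the second nanaomycin array), and for NFE2L2, the gene of NRF2 itself, 0.38 ± 0.07 (0.0242, but 0.116 and 0.104 without the same arrays). CDKN1A, a p53 target that halts the cell cycle, changed by 0.56 ± 0.13 (0.0421, but 0.223 and 0.149 without those arrays, 0.0554 without the first nanaomycin array, 0.0510 with arrays centred on their median, 0.0615 with no filter and 0.0618 with eBayes without the trend). BRD2, BRD3, BCL2 and CAT did not pass with nanaomycin.

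Further lists were not called with nanaomycin. The p53 list had 3 of 19 higher (adjusted p = 0.379), the ribosome biogenesis list 1 of 27 higher (0.149, and 0.0285 with no filter; 0 with the replicate block), the MYC target enzymes 1 of 17 higher and 1 lower (0.311), the polyadenylated histones 3 of 13 higher and 1 lower (0.311), and the BET and P-TEFb list 1 of 13 higher (0.574). The mesenchymal regulators had 3 of 17 higher (0.345), the sympathoadrenal markers 1 of 20 higher (0.667), the BCL2 family 1 of 13 higher (0.590) and the G1/S list 1 of 20 higher (0.961). The metallothioneins (0.857), NF-kB targets (0.624) and reference genes (0.379) had 0 genes passing, as did the 6 lists too short to test. For G1/S the median (0.00335) and the direction of the test (down) differ in sign, as do the median (-0.00509) and the mean (0.0198) of the sympathoadrenal markers and the median (-0.00558) and the mean (0.00675) of the metallothioneins.

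In all, 592 genes rose and 189 fell with nanaomycin, 781 of 11354, of which 58 rises and 9 falls reached 1.5-fold. With the replicate block 310 rose and 80 fell, 386 of them called in both fits, 32 genes passed without the second vehicle array and 73 without the second nanaomycin array, and centring each array on its median gave 412 higher and 341 lower, so that the share of rises went from 75.8% to 54.7%.

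The comparison of both drugs with vehicle gives the joint effect. HMOX1 rose 6.67-fold (2.74 ± 0.26, adjusted p = 4.2e-05), EFNB2 by 2.10 ± 0.14, ELL2 by 2.05 ± 0.14, TUFT1 by 1.91 ± 0.07, PFKFB3 by 1.80 ± 0.12 and HEXIM1 by 1.75 ± 0.06. MYBL1, a MYB family transcription factor gene, rose by 1.70 ± 0.09 and MXD1, whose protein competes with MYC for its partner MAX, by 1.67 ± 0.09. DKK1 fell by 2.67 ± 0.19, PALMD by 2.42 ± 0.10, LMO3 by 2.24 ± 0.14 and RERG by 1.80 ± 0.12. MYCN fell by 0.13 ± 0.02 (adjusted p = 0.00118), BCL2 by 0.78 ± 0.07 and CDKN1A rose by 0.67 ± 0.13. SRXN1 rose by 1.51 ± 0.11, GCLM by 1.62 ± 0.15, TXNRD1 by 0.84 ± 0.03, NFE2L2 by 0.42 ± 0.07, NQO1 by 0.28 ± 0.04, BRD2 by 0.68 ± 0.04 and DNMT3B by 0.48 ± 0.07. BRD3 was higher by 0.19 ± 0.05 (adjusted p = 0.0163), a call lost without the first vehicle array (0.0677) or the first combination array (0.130), and CAT did not pass.

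With both drugs 18 of 27 NRF2 targets rose and 1 fell against vehicle (median 0.28, camera adjusted p = 1.37e-05, adjusted p = 0.502 with an estimated correlation), and 12 of 15 ER chaperone genes rose (median 0.38, camera adjusted p = 1.37e-05, adjusted p = 0.437 with an estimated correlation). DNAJC3 rose by 1.01 ± 0.13 and HSPA5 by 0.73 ± 0.04. Of the adrenergic regulators 19 of 24 fell and 2 rose, 20 and 2 adjusted over the list alone (median -0.35, camera adjusted p = 1.37e-05, adjusted p = 0.502 with an estimated correlation), TFAP2B by 1.55 ± 0.12 and LMO1 by 1.04 ± 0.07. The histone list had 11 of 13 higher (median 0.36, camera adjusted p = 1.37e-05, adjusted p = 0.437 with an estimated correlation) and the BET and P-TEFb list 10 of 13 higher and 1 lower (median 0.40, camera adjusted p = 0.000459, adjusted p = 0.361 with an estimated correlation). Immediate early genes rose in 13 of 15 cases and fell in 2 (median 0.47, camera adjusted p = 0.000459, adjusted p = 0.502 with an estimated correlation), FOS by 1.57 ± 0.09 and EGR1 by 1.27 ± 0.07.

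Integrated stress response genes rose in 12 of 20 cases with both drugs (median 0.23, camera adjusted p = 0.00726, adjusted p = 0.502 with an estimated correlation), SESN2 by 1.17 ± 0.16 and PPP1R15A by 1.19 ± 0.12. In the hypoxia and glycolysis list 9 of 18 rose and 2 fell (median 0.19, camera adjusted p = 0.0172, adjusted p = 0.502 with an estimated correlation). Of the G2/M genes 13 of 19 fell and 1 rose (median -0.20, camera adjusted p = 0.0172, adjusted p = 0.556 with an estimated correlation), among them AURKA by 0.66 ± 0.06 and the mitotic kinase gene PLK1 by 0.47 ± 0.05. Heat shock genes rose in 9 of 15 cases and fell in 1 (median 0.17, adjusted p = 0.572 with an estimated correlation), BAG3 by 1.30 ± 0.14. Their camera adjusted p was 0.0311, 0.0631 without the second vehicle array and 0.173 without the second combination array (median 0.0982). In these lists the counts adjusted over the list alone were the same. The G1/S list, with 3 of 20 higher and 9 lower, had an adjusted p of 0.0510, and of 0.502 with an estimated correlation. It was called with the replicate block (0.0484), quantile normalization (0.0431) or arrays centred on their median (0.0449), without the second vehicle array (0.0370) and without the second combination array (0.0296). The autophagy and lysosome list, with 8 of 16 higher and 2 lower (median 0.15), also had an adjusted p of 0.0510, and of 0.502 with an estimated correlation. It was called with the replicate block (0.0347), with no filter (0.0117) and without the first vehicle (0.0271), first (0.0476) or second (0.0475) JQ1, first (0.0489) or second (0.0489) nanaomycin or first combination array (0.0205).

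Against vehicle, 3096 genes rose and 3063 fell with both drugs, 6159 in all, of which 491 rises and 438 falls reached 1.5-fold.

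The combination against nanaomycin asks what JQ1 changes in cells that also receive nanaomycin. DKK1 fell by 2.40 ± 0.19, SLC7A11 by 1.90 ± 0.32, PALMD by 1.87 ± 0.10, ICAM2 by 1.60 ± 0.07 and SPART by 1.59 ± 0.08. EFNB2 rose by 1.75 ± 0.14, PAG1 by 1.67 ± 0.06, ELL2 by 1.59 ± 0.14, TMEFF2 by 1.53 ± 0.07 and HEXIM1 2.82-fold (SE 0.06 on the log2 scale). HMOX1 was lower with both drugs than with nanaomycin alone, at 12.02 ± 0.64 against 13.15 ± 0.02 (-1.13 ± 0.26, adjusted p = 0.00573), and NQO1 fell by 0.66 ± 0.04 (adjusted p = 8.65e-06). GCLM stood at -0.16 ± 0.15 (adjusted p = 0.400) and MYCN at -0.03 ± 0.02 (adjusted p = 0.279), and neither passed. TXNRD1 was higher by 0.14 ± 0.03 (adjusted p = 0.00616, 0.0612 without the second combination array). SRXN1 was higher by 0.29 ± 0.11 (adjusted p = 0.0471), a call lost without the first nanaomycin (0.260), first combination (0.0621) or second combination array (0.177), with no filter (0.0660) and with eBayes without the trend (0.0674). BRD2 rose by 0.61 ± 0.04, BRD3 by 0.27 ± 0.05 and DNMT3B by 0.63 ± 0.07, BCL2 fell by 0.60 ± 0.07, and CDKN1A, NFE2L2 and CAT did not pass.

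The NRF2 targets split in this comparison: 7 of 27 rose and 8 fell, also adjusted over the list alone, 5 fell with the replicate block, and the list was not called (adjusted p = 0.824). Its median (-0.00529) and mean (-0.0874) lie below 0 while the test points up. EPHX1, an epoxide hydrolase gene, rose by 0.79 ± 0.06. The histone list had 11 of 13 genes higher (median 0.61, camera adjusted p = 3.77e-06, adjusted p = 0.506 with an estimated correlation). The BET and P-TEFb list had 10 of 13 higher and 1 lower, 11 and 1 adjusted over the list alone (median 0.30, camera adjusted p = 0.000142, adjusted p = 0.234 with an estimated correlation). Of the adrenergic regulators 14 of 24 fell and 2 rose (median -0.21, camera adjusted p = 0.00266, adjusted p = 0.639 with an estimated correlation), LMO3 by 1.49 ± 0.14 and TFAP2B by 1.05 ± 0.12. Proteasome genes fell in 16 of 28 cases, 17 adjusted over the list alone (median -0.13, camera adjusted p = 0.00163, adjusted p = 0.639 with an estimated correlation), PSMC2 by 0.33 ± 0.04, PSMC3 by 0.30 ± 0.03 and PSMD11 by 0.27 ± 0.04.

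Immediate early genes rose in 9 of 15 cases and fell in 2 against nanaomycin (median 0.24, adjusted p = 0.639 with an estimated correlation), FOS by 1.02 ± 0.09. Their camera adjusted p was 0.0350, 0.0779 without the first nanaomycin array and 0.119 without the second combination array (median 0.150). In the G1/S list 10 of 20 fell and 1 rose (median -0.14, adjusted p = 0.639 with an estimated correlation), with E2F2 lower by 0.85 ± 0.06. Its camera adjusted p was 0.0369, 0.0843 without the first nanaomycin array and 0.0564 without the first combination array. The ER chaperone list, with 9 of 15 higher and 2 lower (median 0.15), had an adjusted p of 0.0513, and of 0.639 with an estimated correlation. It was called with quantile normalization (0.0472), with no filter (0.0220) and without the first (0.0431) or second (0.0430) vehicle, first (0.0499) or second (0.0497) JQ1, second nanaomycin (0.0226) or first combination array (0.0235). Against nanaomycin 2556 genes rose and 2973 fell, 5529 in all.

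The combination against JQ1 asks what nanaomycin changes in cells that also receive JQ1. HMOX1 rose 11.3-fold (3.50 ± 0.26, adjusted p = 0.00144), GCLM by 1.74 ± 0.15 (adjusted p = 0.00179), SRXN1 by 1.24 ± 0.11 (adjusted p = 0.00179), PFKFB3 by 1.16 ± 0.12 (adjusted p = 0.00848) and EID3 by 1.08 ± 0.11 (adjusted p = 0.00561). TXNRD1 rose by 0.70 ± 0.03 (adjusted p = 4.88e-05) and NQO1 by 0.51 ± 0.04 (adjusted p = 0.00144). SLC7A11 was higher by 1.91 ± 0.32 (adjusted p = 0.0368), a call lost without the second JQ1 array (0.206) or the second combination array (0.187), with no filter (0.0575) and with eBayes without the trend (0.0618) or with robust estimation (0.0520). The linker histone gene H1-3 was lower by 0.71 ± 0.10 (adjusted p = 0.0275, 0.102 and 0.151 without the same arrays). CDKN1A was higher by 0.68 ± 0.13 (adjusted p = 0.0470), a call lost without the second JQ1 array (0.268) or the second combination array (0.283), with quantile normalization (0.0521), arrays centred on their median (0.0506), no filter (0.0699) and eBayes without the trend (0.0723). MYCN, HEXIM1, BRD2, BRD3, BCL2, DNMT3B, NFE2L2 and CAT did not pass.

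Of 27 NRF2 targets 13 rose over all genes and 19 adjusted over the list alone (median 0.22, camera adjusted p = 4.11e-18, adjusted p = 0.187 with an estimated correlation). Heat shock genes rose in 4 of 15 cases, 14 adjusted over the list alone (median 0.25, camera adjusted p = 2.89e-11, adjusted p = 0.187 with an estimated correlation), and ER chaperone genes in 5 of 15, 12 adjusted over the list alone and 3 with the replicate block (median 0.19, camera adjusted p = 1.01e-10, adjusted p = 0.187 with an estimated correlation). Integrated stress response genes rose in 2 of 20 cases, 9 adjusted over the list alone (median 0.21, camera adjusted p = 4.07e-07, adjusted p = 0.233 with an estimated correlation). Immediate early genes rose in 4 of 15, 8 adjusted over the list alone (median 0.19, camera adjusted p = 5.63e-07, adjusted p = 0.187 with an estimated correlation). Of the adrenergic regulators 4 of 24 fell, and 13 fell and 1 rose adjusted over the list alone (median -0.14, camera adjusted p = 3.49e-07, adjusted p = 0.233 with an estimated correlation). Without the second JQ1 array the median was 0.133 for the integrated stress response list (0.322 without the first) and -0.0840 for the adrenergic regulators, and without the second combination array it was 0.116 for the immediate early list.

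Hypoxia and glycolysis genes rose in 2 of 18 cases against JQ1, 7 adjusted over the list alone and 1 with the replicate block (median 0.13, camera adjusted p = 1.55e-05, adjusted p = 0.187 with an estimated correlation). Autophagy and lysosome genes rose in 1 of 16, 5 adjusted over the list alone (median 0.10, camera adjusted p = 6.36e-05, adjusted p = 0.187 with an estimated correlation). The proteasome list had 0 of 28 genes passing over all genes and 3 higher adjusted over the list alone (median 0.06, camera adjusted p = 0.000336, adjusted p = 0.340 with an estimated correlation). G2/M had 0 of 19 passing either way (median -0.09, camera adjusted p = 0.00107, adjusted p = 0.404 with an estimated correlation), and BET and P-TEFb 0 of 13, with 4 higher adjusted over the list alone (median 0.08, camera adjusted p = 0.0267, adjusted p = 0.187 with an estimated correlation). The G2/M median was -0.132 without the first JQ1 array and -0.0383 without the second, and the BET and P-TEFb median 0.0423 without the first JQ1 array and 0.116 without the first combination array. The mesenchymal regulators had 3 of 17 higher (median 0.06, adjusted p = 0.233 with an estimated correlation), with a camera adjusted p of 0.0254, and 0.0858 without the second JQ1 array (median 0.0174; 0.116 without the first). Adjusted over the list alone, 5 rose and 2 fell. The cholesterol synthesis list had 1 of 15 higher, 4 adjusted over the list alone (median 0.02, adjusted p = 0.187 with an estimated correlation), with INSIG1 higher by 0.48 ± 0.06 (adjusted p = 0.0125, 0.102 without the second JQ1 array and 0.132 without the second combination array). Its camera adjusted p was 0.0303, 0.0542 without the second JQ1 array, 0.118 without the first combination array and 0.0550 with arrays centred on their median (median 0.00168; 0.0564 without the second combination array).

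Of the lists not called, the polyadenylated histones (adjusted p = 0.0980) were called without the second combination array (0.0115) and the metallothioneins (adjusted p = 0.0875) without the first JQ1 array (0.0462). Altogether 133 genes rose and 58 fell against JQ1, 191 of 11354, and 23 rises and 3 falls reached 1.5-fold. With the replicate block 81 rose and 16 fell (93 called in both fits), 9 genes passed without the second JQ1 array, 11 without the second combination array and 85 without the first JQ1 array, and arrays centred on their median gave 102 higher and 93 lower.

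**Figure D2:**
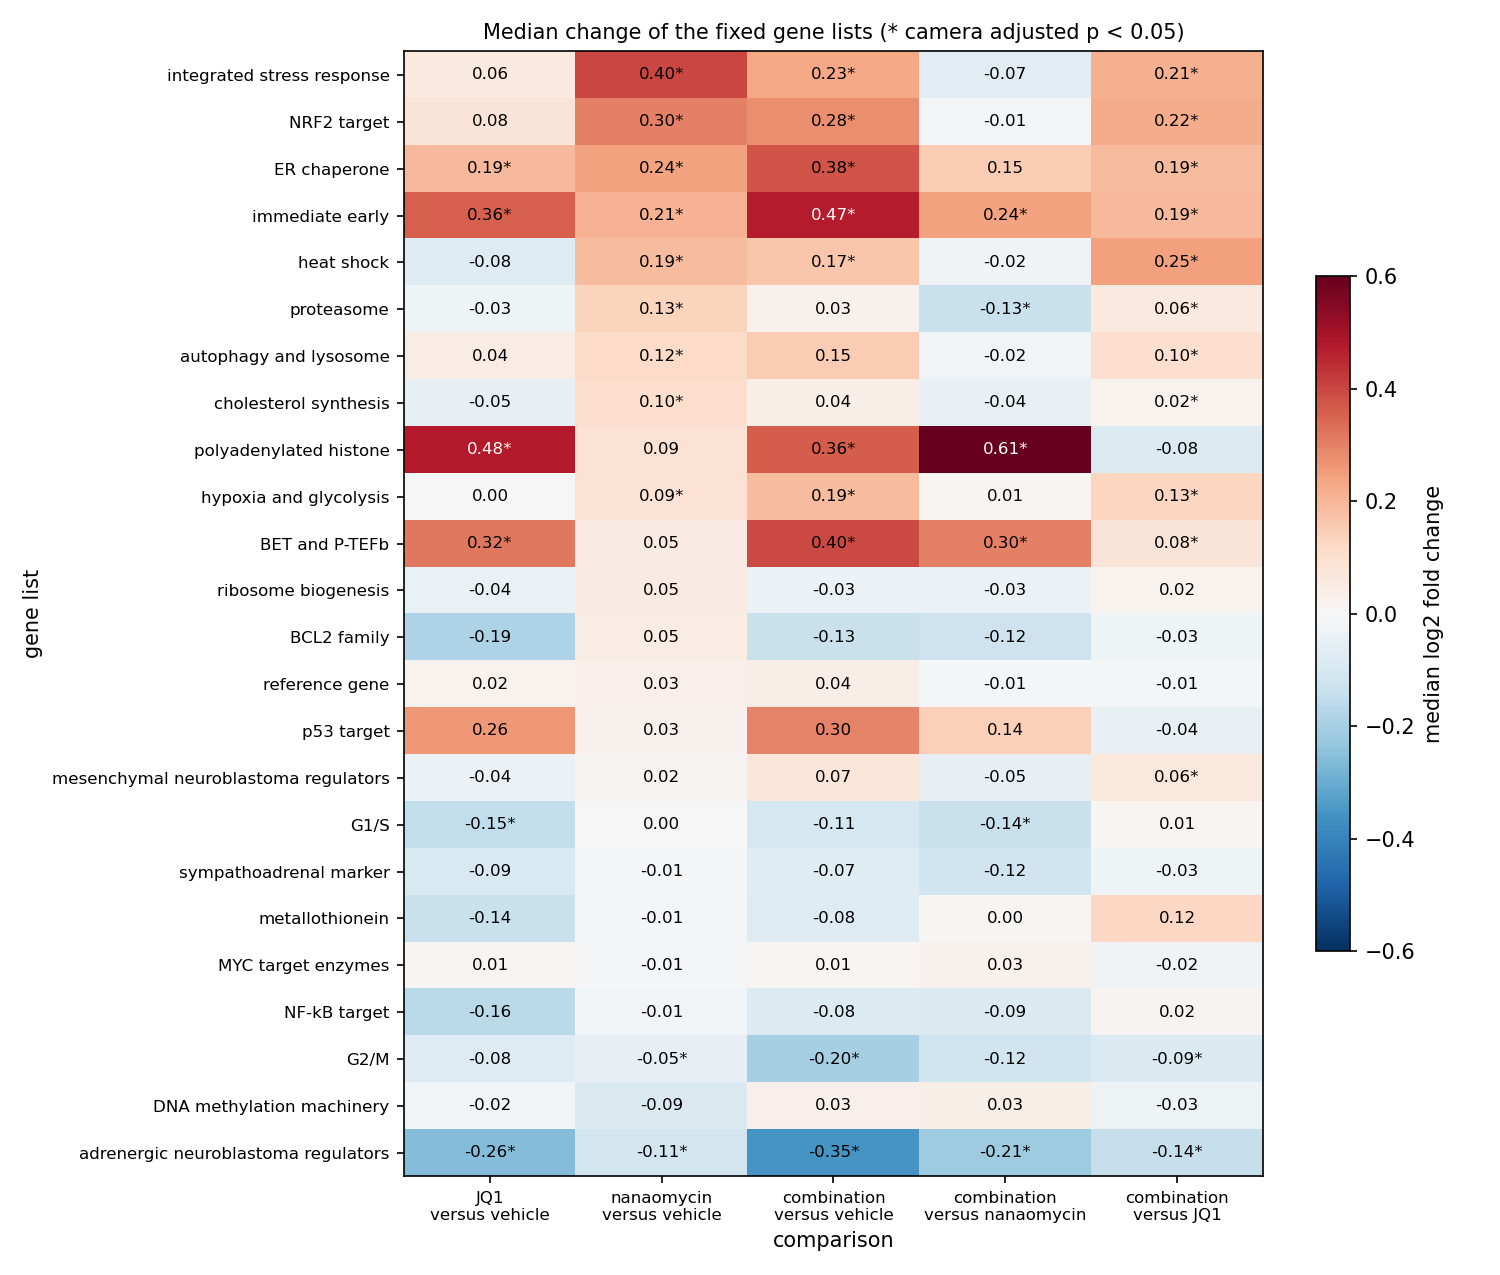
Median log2 fold change (colour and number) of the 24 tested gene lists (y axis) in 5 comparisons (x axis); an asterisk marks a camera adjusted p below 0.05 with the preset correlation. The NRF2 target list has a median of 0.30 with nanaomycin, 0.22 for the combination against JQ1 and -0.01 for the combination against nanaomycin.

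The interaction asks whether the combination differs from the sum of both single effects on the log2 scale. In limma 0 of 11354 genes passed, with 1193 at an unadjusted p below 0.05, and 2 passed in the fit with the replicate block: RNU4-1, an RNA of the spliceosome (0.76 ± 0.08, adjusted p = 0.0743, 0.0350 with the block), and SNORA23 (1.36 ± 0.20, adjusted p = 0.149, 0.0483 with the block). NQO1 followed at -0.43 ± 0.06 (adjusted p = 0.115) and RNU4ATAC at 0.45 ± 0.06 (adjusted p = 0.115). HMOX1 stood at -0.37 ± 0.36 (adjusted p = 0.745), GCLM at -0.04 ± 0.21, SRXN1 at 0.02 ± 0.15, HEXIM1 at -0.06 ± 0.08 and MYCN at 0.02 ± 0.03, and none of them passed. Leaving out the first nanaomycin array gave 5 genes, and leaving out the second vehicle, first JQ1, second JQ1 or second nanaomycin array gave 1 each.

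For the NRF2 targets the interaction had a median of -0.01 and was not called (adjusted p = 0.439, and 0.977 with an estimated correlation). Without the second combination array, which leaves 1 array in that group, the median was -0.0842 and the list was called. The heat shock list had a median of 0.05 and was not called (adjusted p = 0.510, and 0.977 with an estimated correlation). Without the first combination array, which also leaves 1 array in that group, its median was 0.104 and it was called. The MYC target enzymes (adjusted p = 0.236, and 0.792 with an estimated correlation) were called with quantile normalization (0.0456). The lists called for the interaction were the proteasome (median -0.09, camera adjusted p = 2.73e-05, adjusted p = 0.792 with an estimated correlation), the polyadenylated histones (median -0.12, camera adjusted p = 0.0110, adjusted p = 0.792 with an estimated correlation) and the integrated stress response (median -0.13, camera adjusted p = 0.0457, adjusted p = 0.792 with an estimated correlation). In the fry test their adjusted p-values were 0.333 for the proteasome, 0.333 for the histones and 0.623 for the integrated stress response. None of the genes of these lists passed over all genes, and adjusted over the list alone 1 histone gene was lower. The polyadenylated histone call was lost without the second vehicle array (0.0897) or the second nanaomycin array (0.0898), and its median was -0.236 without the second combination array. That of the integrated stress response was lost with arrays centred on their median (0.0515) and without the second vehicle (median -0.0552, adjusted p = 0.276), first JQ1 (-0.0464, 0.640), second nanaomycin (-0.0153, 0.625) or first combination array (-0.0700, 0.292).

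The effect of each drug was also compared between disjoint sets of arrays. The JQ1 effects without and with nanaomycin had a correlation of 0.908 over 11354 genes (covariance 0.0821); 4268 genes were called in both with the same sign and 5 with opposite signs, where independent calls give 1345 with the same sign. For the nanaomycin effects without and with JQ1 the correlation was 0.615 (covariance 0.0128), with 111 genes called in both with the same sign and 1 with opposite signs, where independent calls give 7.90.

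**Figure D3:**
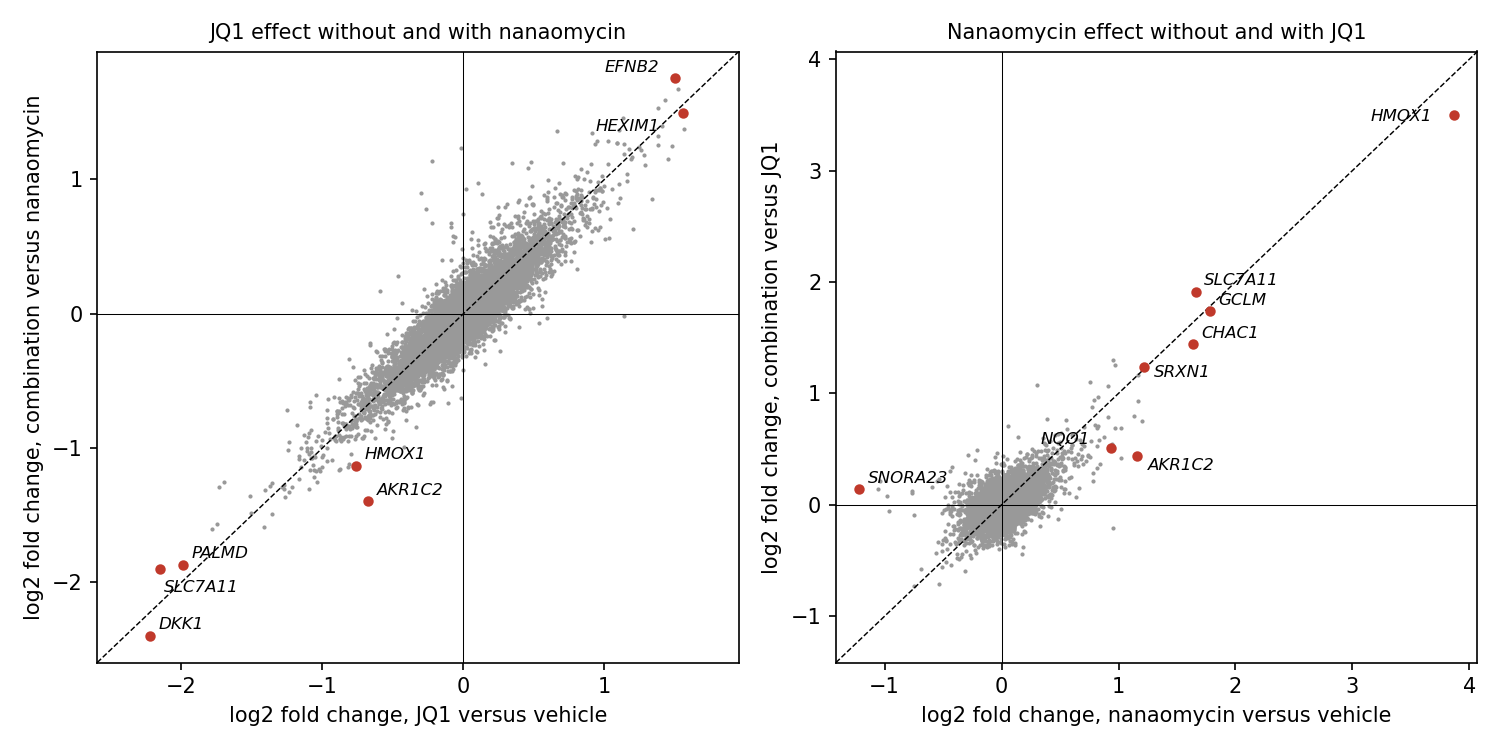
Log2 fold change of 11354 genes for JQ1 without (x axis) and with nanaomycin (y axis, left), and for nanaomycin without and with JQ1 (right); each point is a gene, named genes are red and the dashed line marks equality. The correlations are 0.908 and 0.615.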

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

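The tests of technical explanations for the small nucleolar RNA genes (snoRNA), including the tests on host genes, on spliceosomal RNA genes and on matched random lists, were all chosen only after the result was seen. Of 90 snoRNA genes 19 fell and 3 rose with nanaomycin, 65 lay below 0, and the median was -0.136 (95% interval -0.205 to -0.110, camera adjusted p = 2.96e-08 over 30 class tests, adjusted p = 0.116 with an estimated correlation). For the combination against JQ1, on other arrays, 0 fell and 1 rose, and 31 of 90 lay below 0. The median there was 0.0762 (95% interval 0.0394 to 0.117, camera adjusted p = 0.0132, adjusted p = 0.317 with an estimated correlation). The fall with nanaomycin was thus not seen in cells that also received JQ1. The interaction of both drugs had a median of 0.227, the test of a difference that marked this class, with 17 of 90 below 0 (95% interval 0.137 to 0.299; camera adjusted p = 1.80e-16, adjusted p = 0.0904 with an estimated correlation); it shares the vehicle and nanaomycin arrays with the nanaomycin effect and is not independent of it. Most snoRNAs lie in introns of host genes, and the 32 hosts of 44 of them had a median of 0.0151 (95% interval 0.00617 to 0.0590). On these arrays this argues against a fall of these hosts, though the interval leaves out the spread between arrays. The lowest median of 10000 random lists of the same level, -0.0504, argues against a trend with signal level. A lower recovery of small RNA from the extraction column would lower spliceosomal RNA genes (snRNA) too, and their median of 0.0477 has a 95% interval from -0.237 to 0.124 over 15 genes, wide enough to leave this open beside a drug effect on snoRNA itself. The 21 microRNA genes had a nanaomycin median of -0.0925 (camera adjusted p = 0.0370, adjusted p = 0.670 with an estimated correlation), and 0 of them passed. Their interaction median was 0.0645 (camera adjusted p = 0.0146, 0.670 with an estimated correlation). That of the snRNA genes was 0.0903 (camera adjusted p = 0.00194, 0.392 with an estimated correlation). An interaction above 0 was thus not limited to snoRNA genes.

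The tests of technical explanations for the unnamed probe sets, on signal level and on scaling, were all chosen only after the result was seen. The counts below come from a separate fit to all 32321 probe sets, with no filter and with adjustment over all of them. Of 4091 probe sets with no gene symbol whose IDs lie below the first named probe set, data outside the comparisons above, 815 were higher and 148 lower with JQ1 (561 and 99 with the replicate block). Their median was 0.136. Of 19158 probe sets with 1 gene symbol 2513 were higher and 2634 lower with JQ1. With nanaomycin 7 of the 4091 were higher and 7 lower (0 and 0 with the block). Few probe sets passed there at all, 24 higher and 3 lower of those with 1 gene symbol (4 and 0 with the block), against 592 and 189 genes in the main fit. Against nanaomycin, on other arrays, the combination gave 970 higher and 164 lower. At levels between 4 and 8 the JQ1 median of 1926 of them was 0.285 (95% interval 0.259 to 0.305), while 9325 probe sets with 1 gene symbol at these levels had a median of -0.0579, which argues against a shift of dim signals. Quantile normalization left a median of 0.274, which argues against scaling between arrays; what these probe sets measure is not annotated in the sources used here, and no biological explanation was tested.

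The tests of technical explanations for the proteasome genes were all chosen only after the result was seen. The interaction of both drugs, a test of the difference between the nanaomycin effects with and without JQ1, had a median of -0.0891 over 28 proteasome genes, 26 of them below 0 (95% interval -0.123 to -0.0534, camera adjusted p = 2.73e-05, adjusted p = 0.792 with an estimated correlation). The fry test did not call it (adjusted p = 0.333). Leaving out each array kept the median at or below -0.0596 with a highest adjusted p of 0.0360, which argues against a single array. Random lists of the same level had a median of -0.0290, also below 0, and the proteasome median was at percentile 0.01 of these lists. The 74 mitochondrial ribosomal protein genes, which have no role in the proteasome, had an interaction median of -0.0599 (95% interval -0.102 to -0.0443), at percentile 0.41 of matched random lists, so a shift shared with other gene groups could account for part of the proteasome value. Whether JQ1 weakens the proteasome response to nanaomycin is therefore not settled by these arrays.

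The other results marked by the test of a difference were the interaction medians of the integrated stress response list, -0.127 (18 of 20 genes below 0; 95% interval -0.212 to -0.0829; -0.0153 without the second nanaomycin array, -0.0464 without the first JQ1 array, -0.0552 without the second vehicle array, -0.0700 without the first combination array, -0.211 without the first vehicle array and -0.207 without the first nanaomycin array), and of the polyadenylated histone list, -0.117 (12 of 13 genes below 0; 95% interval -0.245 to -0.0639; -0.236 without the second combination array). Some of the integrated stress response medians with an array left out lay outside its interval, which resamples genes and not arrays. Groups of 2 arrays are too small for a test of single arrays that stand apart.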

How the results depend on the processing

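No called result reversed its direction under any alternative. Of 633 results on named genes 368 passed the threshold, and 272 of these passed under every alternative in which they were tested; each of the other 96 was lost when at least 1 array was left out, 17 with the replicate block, 8 in the fit to only the 2 groups and 41 under other settings. Of 144 list results 49 were called. All 49 lost their call with an estimated correlation, 10 when an array was left out, 0 with the replicate block and 18 under other settings (10 in fry, 10 with the upper 30% of probe sets, 2 with centred arrays and 1 with the mean of a gene's probe sets). The filter, which changes the members measured, moved some called medians: with no filter, those of the immediate early list went from 0.360 to 0.132 with JQ1, from 0.240 to 0.100 for the combination against nanaomycin and from 0.192 to 0.123 against JQ1, and that of the polyadenylated histones from 0.614 to 0.345 against nanaomycin. With the upper 30% the integrated stress response median with nanaomycin went from 0.401 to 0.220 and that of the hypoxia and glycolysis list from 0.192 to 0.0762 for both drugs and from 0.129 to 0.0410 against JQ1, where both calls were lost. The mesenchymal regulators against JQ1 went from 0.0640 to 0.166 with the upper 30%, and the G2/M list with nanaomycin from -0.0487 to -0.0769 with centred arrays. Lists not called gained a call in 23 cases in fry, 3 with no filter, 3 with quantile normalization, 1 with centred arrays and 2 with the replicate block. Leaving out an array also gave calls to lists not called before, which are not counted here. The NRF2 target list with nanaomycin, at a median of 0.301 (0.428 with the upper 30% and 0.417 with the mean of a gene's probe sets), had an adjusted p of 0.232 with an estimated correlation, which does not enter the median; the estimate rests on 4 residual degrees of freedom. The ribosome biogenesis list with JQ1, at a median of -0.0386, passed only in fry (adjusted p = 0.0434), which tests the list by itself and not against other genes. Testing only the upper 30% of probe sets, 6932 genes, gave 3648 changed genes with JQ1, 4028 with both drugs and 1 for the interaction, with fewer genes tested. For the combination against JQ1 the 191 changed genes became 46 with no filter, 64 with eBayes without the trend and 646 in a fit to only the 2 groups compared, and the cause was not tested. That last fit has no interaction. Apart from the replicate block and left-out arrays, the remaining settings kept the counts of changed genes within 1.5 times. Counts of rises or falls alone could move more. With the upper 30%, falls for the combination against nanaomycin went from 2973 to 1935. A separate fit to all 32321 probe sets called 24 higher and 3 lower with nanaomycin among 19158 with 1 gene symbol. The main fit called 592 and 189 genes, and the cause of this difference was not tested.

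Where an array was left out, the lone array of its group was assumed to vary like the other groups. Changed genes then ranged from 4215 to 5567 for JQ1, from 32 (without the second vehicle array) to 953 (without the first) for nanaomycin, from 4538 to 6171 for both drugs against vehicle, from 4106 to 5575 against nanaomycin, from 9 (without the second JQ1 array) to 256 (without the second vehicle array) against JQ1, and from 0 to 5 for the interaction. With fewer arrays the tests have less power, but which array was left out also mattered, and the cause was not tested. The NRF2 target median ranged from 0.247 to 0.356 with nanaomycin and from -0.0405 to 0.0299 for the combination against nanaomycin. The ribosome biogenesis median with JQ1 ranged from -0.0432 to -0.00400. Probe sets below the limit on mean level were left out of these counts, so genes expressed at a low level are outside them.

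The replicate block gave 390 changed genes with nanaomycin, 97 for the combination against JQ1 and 2 for the interaction, where the fit without it gave 781, 191 and 0. It kept all other counts of changed genes within 1.5 times and ended no call of a list. For both drugs against vehicle it added the G1/S list (adjusted p = 0.0484) and the autophagy and lysosome list (adjusted p = 0.0347). Without the block, camera with an estimated correlation gave both lists an adjusted p of 0.502. Because the values already have nearly equal means for both replicate numbers, the block removes little spread. An adjustment that made them equal would already have used the degree of freedom that the block takes. The fit without the block does not count that loss. For JQ1 versus vehicle the median standard error was 0.0594 without the block and 0.0748 with it. In the simulated comparison without changed genes, 9.19% of genes had p below 0.05 without the block and 4.92% with it. The standard errors and p-values of the fit without the block therefore tend to be too small. The correlations of replicate differences between groups ran from -0.476 to -0.218 and give no hint on pairing, since the same adjustment forces their mean to about -0.333.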

Other observations

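Gene groups outside the fixed lists were looked at only after the data had been seen, so the counts here describe these arrays. Of 15 measured snRNA genes, whose RNAs form the core of the spliceosome, 12 rose with JQ1 (median 0.54, 95% interval 0.22 to 0.78; camera adjusted p = 0.000191 over 30 class tests, adjusted p = 0.317 with an estimated correlation). Against vehicle 14 of the 15 rose with both drugs (median 0.75, adjusted p = 4.58e-05, adjusted p = 0.317 with an estimated correlation). The snoRNA genes had 65 of 90 higher and 1 lower for the combination against nanaomycin (median 0.36, adjusted p = 2.17e-11, adjusted p = 0.0933 with an estimated correlation). With JQ1 against vehicle 23 of 90 were higher and 2 lower (median 0.098, camera adjusted p = 0.0147, adjusted p = 0.317 with an estimated correlation). Whether the recovery of small RNA differed between arrays with and without JQ1 was not tested. Among 55 histone genes of all types 39 rose and 0 fell with JQ1 (median 0.27, adjusted p = 1.88e-09 over 129 name families, adjusted p = 0.970 with an estimated correlation).

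Among 48 genes of the large mitochondrial ribosomal subunit (MRPL) 20 fell and 2 rose with JQ1 (median -0.10, adjusted p = 0.0425, adjusted p = 0.970 with an estimated correlation), and 27 fell and 1 rose for the combination against nanaomycin (median -0.18, adjusted p = 8.01e-05, adjusted p = 0.961 with an estimated correlation). In the same comparison 8 of 11 MCM genes, most of them subunits of the replication helicase, and 9 of 13 LSM genes, which act in RNA processing, fell and 0 rose (adjusted p = 0.0385 for each, adjusted p = 0.961 with an estimated correlation). Of 10 HSPA genes, the HSP70 family, 4 rose with nanaomycin (median 0.16, adjusted p = 0.00455, adjusted p = 0.933 with an estimated correlation). The aldo-keto reductase gene AKR1C2 had means of 7.71 with vehicle, 7.04 with JQ1, 8.87 with nanaomycin and 7.48 with both drugs; it fell by 0.68 ± 0.07 (SE) with JQ1 and by 1.40 ± 0.07 for the combination against nanaomycin, and its interaction term of -0.72 ± 0.11 did not pass (adjusted p = 0.149).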
